A study of Mus musculus with 5 samples.

How the data were processed

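RNA was profiled from cerebellar tumour cells of Math1-Cre;Gli2A mice kept on a doxycycline diet from conception (embryonic day 0). Per the labels' protocols, cells were isolated from cerebella once tumours had developed, digested with papain, and used for RNA extraction at once. Strand-specific mRNA libraries were then made. The labels put all 5 libraries in 1 group, in which GLI2 is active, so no comparison between conditions could be made. The libraries are named here by the tumour numbers in their titles: 1, 5, 8, 14 and 15. The labels do not state that each number is a separate animal. Errors and p-values taken over the 5 libraries therefore measure the spread between these samples, part of which may be technical. Standard errors over genes, and p-values from random gene lists or gene sets, do not measure that spread. The standard errors over genes are computed as for a mean, although they stand beside medians.

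The deposited table holds 17739 genes by symbol. Its values are on a log2 scale and range from 0.33 to 16.9 in the 5 columns used. The deposited log2 values are read here as DESeq2 regularised-log values, from the short name of the table in the labels and from the tools in the submitters' processing notes; no source used here states the transformation outright. The submitters' processing notes also name STAR 2.4.1, featureCounts from Subread 1.4.6, and the builds mm10 and GRCm38. The annotation, the strand setting, the filter on genes and the DESeq2 version are not given in the sources used here. The regularised log corrects for library size but not for transcript length. It also pulls the values of weakly expressed genes towards the gene's mean over the libraries transformed together, so a difference at a low-count gene is understated. The table has 7 columns, of which 2 match no sample in the labels. These 2 were not used in any step, although they may have entered the transformation. Read counts were not used here, so the depth of each library is unknown and no counting interval is given. The column medians lay between 8.51 and 8.58.

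Gene lists, pairs of genes, tests and the rule for named genes were fixed before the data were examined. There were 33 lists with 331 different genes, of which 322 were in the table. Among those not in the table were 4 of 8 T cell markers and 4 of 7 red blood cell markers (the globins). Some genes sit in more than one list. For example, Hhip, Sfrp1 and Pdlim3 are SHH targets and SHH classifier genes, Atoh1 is a progenitor and classifier gene, and Hes1 and Hes5 are in the neural stem cell and Notch lists. The rule named Gli2, the genes of 14 fixed pairs, and every member of the SHH target and subgroup classifier lists. From each list it took the 2 members with the highest mean and the 1 with the lowest, and the 3 of largest standard deviation (SD) where the list was called more variable. It added the 10 genes of highest mean and the 15 of largest SD among those with a mean of at least 5. A few genes that the rule names, and 2 of the pairs, are not reported here.

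For each tumour the median of each list was taken. A list's level was placed among the medians of 10000 random lists of the same size. Differences between lists, and between paired genes, were taken within each tumour and tested with an exact two-sided sign-flip permutation test. With 5 tumours there are 32 sign patterns, so the smallest p this test can give is 0.0625 and no such comparison can pass 0.05. Adjustment was by Benjamini-Hochberg within the family of 5 list differences and the family of 14 pairs. The spread of a list was the median over its genes of the SD between tumours. It was compared with 10000 random lists matched on mean level in 20 bins, among the 13691 genes with a mean of at least 5 and for lists with at least 3 such genes, with adjustment over the 31 lists this left. Genes of a list vary together, unlike those of a random list, so these p-values describe the list in these 5 libraries. The smallest p that the random lists can give is 1e-04. Counts of list members highest or lowest in 1 tumour were compared with random lists in the same way. That comparison was chosen after seeing the data and adjusted over 310 tests.

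Gene positions, exon lengths and chromosomes came from GENCODE M21 on GRCm38, the build the submitters name. Of the table's symbols, 97.5% matched exactly 1 annotated gene. For each tumour and chromosome the median over genes of the tumour's value minus the median of the other 4 tumours was compared with 10000 random gene sets. A shift was called where it exceeded 0.2 with an adjusted p under 0.05, over 105 tests. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

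The steps were tested on simulated data drawn around the real gene means. For the count of genes varying over 4-fold among 13691 genes, 100 of 100 genes shifted by 3 log2 units in 1 library were recovered, and 1 of 100 shifted by 1.5. For the list spreads, 20 of 20 lists with a spread raised 2-fold were recovered, with 1 false call among 20 other lists. The simulated genes varied independently, each with the typical spread of its level. This count of false calls therefore does not carry over to real lists, whose genes vary together. A chromosome lowered by 0.3 was recovered with 0 false calls. List levels were also placed among genes with a mean of at least 5 and after subtracting log2 exon length. Other alternatives were list means, subtraction of log2 exon length, other filters on low values, quantile normalisation, other measures of spread, and leaving out each tumour in turn.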

Results

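The series addresses the role of GLI2, a transcription factor at the end of the Sonic hedgehog (SHH) pathway, in SHH medulloblastoma, a cerebellar tumour. Math1-Cre acts in granule neuron progenitors, and the tumours arose in Math1-Cre;Gli2A mice fed doxycycline from conception, with GLI2 active per the labels. Gene expression was measured in 5 tumours of this single group (tumours 1, 5, 8, 14 and 15) on a log2 scale, in values read here as regularised-log values. The design therefore shows which genes these tumours expressed, how gene groups compared within each tumour, and how far tumours of 1 genotype and treatment differed. Of 17739 genes, 13691 (77.2%) had a mean of at least 5. The 10 genes of highest mean included Eef1a1 (16.77 ± 0.11, SD, n = 5), Tuba1a, Hsp90ab1, Actb, Tubb5, the imprinted gene Nnat and Rn45s, a ribosomal RNA precursor (15.50 ± 0.11).

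Targets of the SHH pathway stood high in all 5 tumours. The median of the 15 genes listed as targets was 12.22 ± 0.17 (SD, n = 5), above each of 10000 random gene lists. Of the 15, 12 had a mean of at least 10. Ptch1, the SHH receptor and a feedback target (GRCm38 chromosome 13, 63508328 to 63573598, protein coding), averaged 14.47 ± 0.32. Ccnd2 and Ccnd1, cyclins that drive entry into the cell cycle, averaged 14.27 ± 0.27 and 13.18 ± 0.35. Gli1 (chromosome 10, 127329882 to 127341974), a transcriptional effector whose own expression is a readout of the pathway, averaged 12.27 ± 0.25. Mycn averaged 12.24 ± 0.13 and Hhip, a feedback inhibitor, 11.97 ± 0.54. The lowest gene of the target list was Hhat, at 6.42 ± 0.12. Pathway components as a list (median 8.89 ± 0.20) lay at the 64.6th percentile of random lists, at 39.3 among genes with a mean of at least 5 and at 48.8 with exon length subtracted. Among them Sufu averaged 11.99 ± 0.09, Prkaca 11.58 ± 0.08 and Dhh, a hedgehog ligand, 1.92 ± 0.02.

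Among the GLI factors, Gli1 and Gli2 far exceeded Gli3 in every tumour. Gli2 (chromosome 1, 118834132 to 119053619) averaged 11.39 ± 0.11, with values within 0.29 of each other. The labels do not say whether transcripts of the Gli2A allele would be counted under this symbol. Gli2 exceeded Gli3 by 4.69 ± 0.27 and Gli1 exceeded Gli3 by 5.56 ± 0.29 on the log2 scale. Gli1 exceeded Gli2 by 0.87 ± 0.19, or 1.33 after subtracting log2 exon length. Mycn exceeded Myc by 2.50 ± 0.16, and the co-receptor gene Boc exceeded Cdon by 4.67 ± 0.33. Ccnd2 exceeded Ccnd3 by 4.02 ± 0.38. The difference of Ccnd1 minus Ccnd2 was -1.10 ± 0.32, and -0.10 ± 0.32 after subtracting exon length, when it stayed below 0 in 3 of 5 tumours. Among other transcription factors and cell cycle inhibitors, Pax6 exceeded Pax2 by 8.61 ± 0.44 and Cdkn1b exceeded Cdkn2c by 2.35 ± 0.15. Sox2 minus Sox11 was -3.34 ± 0.39, or -1.33 after subtracting exon length. Without the subtraction, all 14 pairs had the same sign in 5 of 5 tumours, and each gave the smallest p the exact sign-flip permutation test allows, 0.0625 (adjusted 0.0625 over 14 pairs). Levels of different genes also depend on transcript length.

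The human medulloblastoma classifier genes of the SHH, WNT, Group 3 and Group 4 subgroups were then compared within each tumour. With no tumour of another subgroup for reference, this gives the relative levels of the lists. It cannot assign these tumours to a subgroup. The SHH classifier genes exceeded those of Group 3 by 2.71 ± 0.60 and those of Group 4 by 1.06 ± 0.73, in 5 of 5 tumours each. Both differences gave an exact sign-flip permutation p of 0.0625, adjusted 0.0781 over 5 list differences. The size depended on the summary: with list means the differences were 4.60 and 2.99, and with exon length subtracted 4.75 and 2.50. Without genes under a mean of 5 they were 2.13 ± 0.92, above 0 in 5 of 5 tumours, and 0.79 ± 0.93, above 0 in 4 of 5. The SHH genes spanned a wide range, from Sfrp1 (13.83 ± 0.13) and Hhip (11.97 ± 0.54) to Atoh1 (8.62 ± 0.67), Pdlim3 (8.58 ± 0.49) and Eya1 (7.86 ± 0.26). In Group 3, Nrl, a photoreceptor factor, averaged 2.67 ± 0.04 and Gabra5 3.63 ± 0.02, and Mab21l2 was the highest at 8.95 ± 0.16. In Group 4, Kcna1, a potassium channel gene, averaged 9.38 ± 0.47, Rbm24 9.33 ± 0.24 and Eomes 7.44 ± 0.25.

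The SHH classifier median did not exceed that of the WNT classifier. The difference was -0.62 ± 0.49, below 0 in 4 of 5 tumours and 0.09 in tumour 14 (exact sign-flip permutation p = 0.125, adjusted 0.125). Of the 4 WNT classifier genes in the table, Wif1, a secreted WNT inhibitor, averaged 10.54 ± 0.53, and Tnc, an extracellular matrix gene, 10.54 ± 0.59. Dkk2 averaged 8.22 ± 0.67 and Gad1 6.31 ± 0.11. The remaining WNT classifier gene, Emx2, is not in the table, for a reason not given. If its level were below that of Dkk2, Dkk2 would be the middle gene of the WNT list by mean. Its mean lies below the SHH classifier median (8.72 ± 0.57), so the sign may rest on the missing gene. The sign of the SHH minus WNT difference also depended on the summary. With list means it was 1.27 ± 0.21, and after subtracting log2 exon length it was 0.58 ± 0.58.

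**Figure D1:**
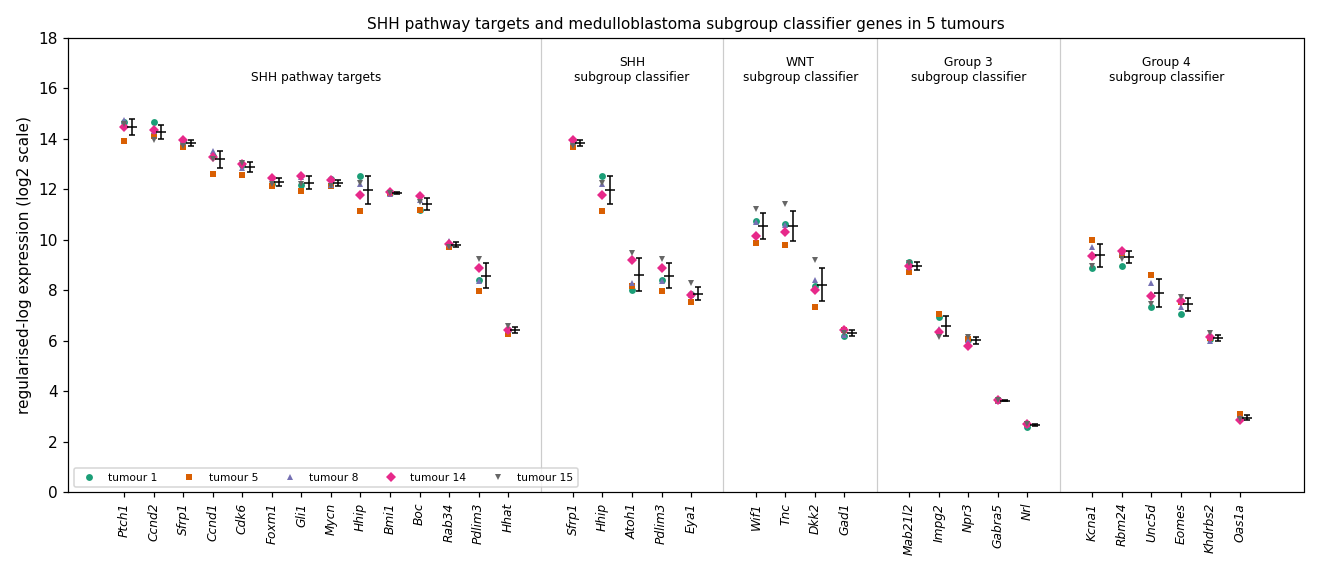
Regularised-log expression (vertical axis, log2 scale) of SHH pathway targets and of the 4 medulloblastoma subgroup classifier lists in the 5 tumours. Each symbol is 1 tumour and the black bars show the mean ± SD (n = 5). Ptch1 averaged 14.47 and Nrl of the Group 3 list 2.67. Hhip was lowest in tumour 5, and Wif1, Tnc and Dkk2 were highest in tumour 15.

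Along the granule neuron lineage, progenitor and early differentiation genes were both abundant and genes of mature granule neurons were lower. The progenitor list had a median of 12.22 ± 0.14, led by Zic1 (15.08 ± 0.05) and Zic2 (13.93 ± 0.08), transcription factors of cerebellar granule progenitors. The differentiating list reached 13.36 ± 0.17, led by the adhesion gene Cntn2 (14.27 ± 0.22) and Tubb2b (14.16 ± 0.09). Neurod1, which drives granule neuron differentiation, averaged 14.16 ± 0.07. Atoh1 minus Neurod1 was -5.54 ± 0.62, and Neurod1 exceeded Gabra6 by 7.41 ± 0.65. The mature list had a median of 9.88 ± 0.24, still at the 94.1th percentile of random lists. Among genes with a mean of at least 5 this list lay at the 77.55th percentile, and with exon length subtracted at the 81.21th. Within it Rbfox3 averaged 12.98 ± 0.15, whereas Gabra6, a receptor subunit of mature granule cells, averaged 6.74 ± 0.65. Progenitor genes exceeded mature genes by 2.34 ± 0.15 and lay below differentiating genes, with a difference of -1.14 ± 0.24. Both held in 5 of 5 tumours (exact sign-flip permutation p = 0.0625, adjusted 0.0781). With list means the differences were 1.38 and -1.85, and without genes under a mean of 5 they were 2.75 and -0.73.

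Genes of dividing cells were expressed highly. The cell cycle list had a median of 11.10 ± 0.15 and the DNA replication list 11.56 ± 0.15, at the 99.98th percentile and above all random lists. Mki67, a proliferation marker, averaged 14.00 ± 0.16, Top2a 13.32 ± 0.14 and Mcm7 12.56 ± 0.12. Among cell cycle inhibitors and tumour suppressors, Cdkn1b averaged 12.55 ± 0.03 and Trp53 12.01 ± 0.10, while Cdkn2a stood at 4.56 ± 0.13. Of the p53 target genes, Cdkn1a averaged 11.34 ± 0.26 and Mdm2 10.76 ± 0.08.

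Markers of other cell types were also present in every tumour. Oligodendrocyte markers had a median of 10.52 ± 0.47, with Mbp, a myelin protein gene, at 14.08 ± 0.60. Oligodendrocyte precursor markers reached 11.55 ± 0.24, led by Pdgfra (12.67 ± 0.25). Astrocyte and Bergmann glia markers (10.87 ± 0.33) were led by Sparcl1 (14.09 ± 0.16). Microglia and macrophage markers (10.05 ± 0.35) were led by Csf1r (11.24 ± 0.32), and pericyte and fibroblast markers (10.11 ± 0.12) by Col3a1 (13.27 ± 0.54). T cell markers (median 3.67 ± 0.11 over 4 genes) and interferon response genes (5.47 ± 0.18) were among the lowest lists, at the 2.9th and 2.78th percentiles of random lists. Among genes with a mean of at least 5, which 1 of the 4 T cell genes reached, the percentiles were 8.75 and 0.01, and with exon length subtracted 0.87 and 2.4. The choroid plexus gene Ttr averaged 13.43 ± 0.72, against 5.04 ± 0.40 for Kcne2. Endothelial (9.08 ± 0.33), Purkinje cell (7.24 ± 0.29), unipolar brush cell (7.49 ± 0.44), GABAergic interneuron (4.99 ± 0.17) and antigen presentation genes (7.05 ± 0.30) lay lower, as did hypoxia and glycolysis (8.83 ± 0.28), WNT target (9.05 ± 0.31) and Notch pathway genes (9.27 ± 0.25). Immediate early and dissociation stress genes stood at 11.96 ± 0.24, above all random lists, with Jun at 14.69 ± 0.29 and Egr1 at 14.53 ± 0.22.

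**Figure D2:**
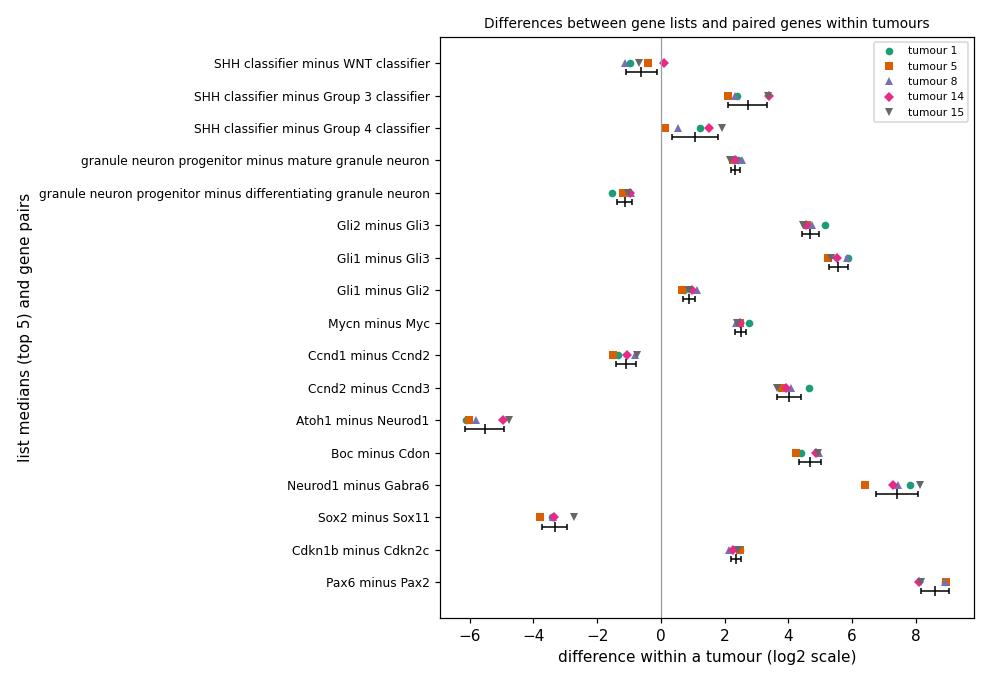
Differences within each tumour on the log2 scale (horizontal axis) between list medians (top 5 rows) and between paired genes (lower 12 rows). Symbols are tumours, black bars are the mean ± SD (n = 5), and the vertical line marks 0. SHH minus WNT classifier genes lies below 0 in 4 of 5 tumours, and each gene pair shown keeps 1 sign in 5 of 5.

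For 22 of the 31 gene lists tested, expression differed more between tumours than for random genes of like level. The SD between tumours of a typical gene was 0.11, a 1.08-fold difference. The median SD was 0.24 for SHH targets, 0.54 for oligodendrocyte markers, 0.41 for choroid plexus markers and 0.35 for immediate early genes. None of 10000 matched random lists reached the spread of any of these 4 lists (random-list permutation p = 1e-04, the smallest it can give, adjusted p = 0.000387). The 22 lists passed the threshold of 0.05 for a larger spread. Some of the 22 calls rested on 1 tumour: choroid plexus and microglia were not called without tumour 5, unipolar brush cell without tumour 1, cell cycle without tumour 14, and differentiating granule neuron and sex-linked genes without tumour 8. WNT target genes were not called without tumour 8, 14 or 15, without a filter on low values or by the range. By the median absolute deviation, microglia, choroid plexus and sex-linked genes were not called. The other 9 lists did not pass, among them granule neuron progenitor genes (median SD 0.09, adjusted p = 0.62), SHH pathway components (0.14, adjusted p = 0.124) and p53 targets (0.15, adjusted p = 0.0634). Of 11 alternative settings, 7 called the Group 4 classifier genes, 5 the p53 targets, 4 the Purkinje cell markers, 3 the SHH pathway components and 0 the progenitor genes. No list passed for a smaller spread: 0 of 31 with adjustment and 0 at an unadjusted p under 0.05 by the random-list permutation.

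Tumour 5 had the lowest SHH target levels and the highest levels of several markers of other cells. SHH targets were lowest there for 12 of 15 genes, against 5.18 in matched random lists (adjusted p = 0.00886, random-list permutation), with a median deviation from the other 4 tumours of -0.38 ± 0.08 (standard error over genes). Hhip was 11.13 in tumour 5 and up to 12.52 in tumour 1, and Ptch1 was 13.92 against up to 14.73. Cell cycle genes were lowest in tumour 5 for 12 of 15 genes (adjusted p = 0.00715), by a smaller median deviation of -0.21 ± 0.02. Oligodendrocyte markers were highest in tumour 5 for 9 of 9 genes and microglia and macrophage markers for 13 of 14 (adjusted p = 0.00517 each), with median deviations of 0.76 ± 0.13 and 0.65 ± 0.04. Choroid plexus markers were highest there for 7 of 8 genes, mature granule neuron genes for 10 of 14 (adjusted p = 0.00715 each) and endothelial markers for 8 of 10 (adjusted p = 0.0155). Gabra6 spanned 3.14-fold, Grin2c 3.12-fold and Mobp 3.67-fold between the highest and lowest tumours. Interferon response genes were also highest in tumour 5 for 7 of 8 genes (adjusted p = 0.0366). Neural stem cell genes were lowest there for 8 of 10 genes (adjusted p = 0.0172). Of the pericyte and fibroblast markers, 9 of 11 lay below the other tumours in tumour 5 and 2 above, with a median deviation of -0.23 ± 0.13. The list's median was nevertheless highest there, at 10.24 against 9.96 to 10.20. The counts of genes highest or lowest in a tumour were chosen after seeing the data. Those given with an adjusted p had unadjusted p-values between 1e-04 and 0.0026 by the random-list permutation.

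The other 4 tumours each had groups at an extreme. In tumour 1 immediate early and dissociation stress genes were lowest for 12 of 12 genes (adjusted p = 0.00517), with a median deviation of -0.70 ± 0.06, and oligodendrocyte markers for 8 of 9 (adjusted p = 0.00517). Oligodendrocyte precursor markers were highest in tumour 1 for 6 of 7 genes (adjusted p = 0.0212), and Gpr17 there was 2.84-fold above the lowest tumour. In tumour 15 neural stem cell genes were highest for 7 of 10 genes (adjusted p = 0.00715) and Notch pathway genes for 8 of 10 (adjusted p = 0.00715). Immediate early and dissociation stress genes were also highest there for 6 of 12 genes, against 1.53 in random lists (adjusted p = 0.0294). The list's median was nevertheless highest in tumour 8, at 12.18 against 12.08 in tumour 15, with median deviations of 0.25 ± 0.07 and 0.19 ± 0.13. Sox1, Nes and Fabp7 each peaked in tumour 15, with 1.88-fold, 1.83-fold and 1.85-fold spans. Microglia and macrophage markers were lowest in tumour 15 for 13 of 14 genes (adjusted p = 0.00517). In tumour 14 DNA replication genes were highest for 12 of 16 genes (adjusted p = 0.00517) and cell cycle genes for 10 of 15 (adjusted p = 0.0164). Antigen presentation genes were lowest in tumour 14 for 6 of 9 genes (adjusted p = 0.0366), and Cd74, the class II invariant chain, spanned 3.22-fold. Endothelial markers were lowest in tumour 14 for 6 of 10 genes (adjusted p = 0.0145) and pericyte and fibroblast markers for 6 of 11 (adjusted p = 0.00715). In tumour 8 differentiating granule neuron genes were lowest for 9 of 12 genes (adjusted p = 0.00715), by a median deviation of -0.22 ± 0.03. The adjusted p-values for single tumours came from the random-list permutation.

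**Figure D3:**
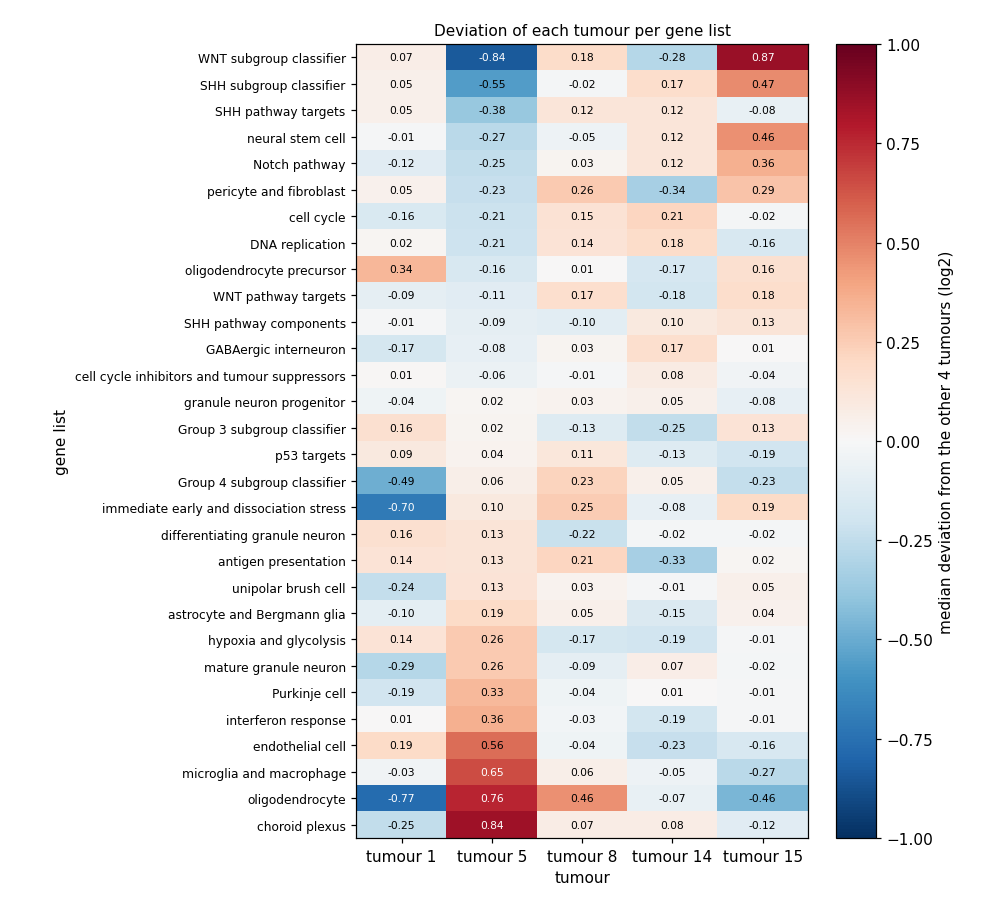
Median deviation of each tumour (columns) from the median of the other 4 tumours for each gene list (rows), over list genes with a mean of at least 5; colour and printed numbers give log2 units. Lists are ordered by tumour 5. Oligodendrocyte markers are 0.76 above the others in tumour 5 and 0.77 below in tumour 1, and immediate early genes are 0.70 below in tumour 1.

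Few single genes varied strongly. The range over the 5 tumours exceeded 4-fold for 21 of 13691 genes and 2-fold for 519 (3.79%). Of the 21 genes, 5 were the sex-linked genes Xist, Eif2s3y, Ddx3y, Kdm5d and Uty. Xist, the RNA that silences an X chromosome in females, was 12.89 in tumour 8 and 7.29 to 8.10 in the others, and Ddx3y, on the Y chromosome, was 6.61 in tumour 8 and 9.78 to 10.03 in the others. The labels do not give the animals' sex. Of the other 16 genes, 11 were lowest in tumour 5, and without tumour 5 the count fell from 21 to 9. The genes lowest in tumour 5 included Hapln3 (5.28-fold), Aldh3b2 (4.93-fold), Sfrp5, a secreted WNT modulator (4.48-fold), Foxl1, a hedgehog-responsive mesenchymal factor (4.31-fold), the imprinted RNA H19 (4.31-fold), Coch (4.17-fold) and the serotonin receptor gene Htr3a (4.08-fold). Fam107a (5.07-fold), Ptgds, a prostaglandin D synthase gene (5.02-fold), Gabrd (4.39-fold) and Calb2 (4.35-fold) were highest in tumour 5.

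Across genes, which are not replicates, Pearson correlations between tumours ran from 0.986 (tumours 5 and 15) to 0.995 (tumours 8 and 14). Levels differ far more between genes than between tumours, so high correlations say little about likeness. Among genes with a mean of at least 5, tumours 5 and 15 lay over 2-fold apart at 323 genes and tumours 8 and 14 at 32. The first principal component held 45.4% of the variance and set tumour 5 against tumour 15. No pair of libraries had an identical value at any gene with a mean of at least 5. Chromosome-wide shifts of expression in 1 tumour were then sought. Only chromosome Y in tumour 8 was called, by -3.20 (adjusted p = 0.0035, random-set permutation). This call rests on 4 genes, Eif2s3y, Ddx3y, Kdm5d and Uty, which are the Y-linked genes of the sex-linked list above. Xist in the same tumour was 12.89, against 7.29 to 8.10 in the others. The largest deviation of an autosome in any tumour was 0.03, below the 0.2 set as the smallest shift. Of 105 tests, 9 had an adjusted p under 0.05, including chromosome X in tumour 8 at -0.05 over 479 genes (adjusted p = 0.0035).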

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

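Tests for an outlying tumour were applied to 235 results: 33 list medians, 17 differences and 185 named genes. A result is given here where the highest or lowest tumour's gap to its nearest neighbour, divided by the whole range, exceeded 0.71. Chance gives about 1 in 20, or 11.8 results, and 17 exceeded it. This shows no excess over chance, since some genes were named for their large SD and the results are not independent. The sex-linked list and its 5 genes, for example, are 1 observation in tumour 8. The tests of explanations in this part were chosen after the results were seen.

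Tumour 8 stood apart at the sex-linked list (ratio 0.977) and its genes Kdm5d (0.98), Uty (0.969), Ddx3y (0.926), Eif2s3y (0.918) and Xist (0.855). Tumour 5 stood above the others at choroid plexus markers (0.899, a median of 8.79 against 7.98 to 8.06), with Ttr at 0.903 and Enpp2 at 0.828. It also stood above them at interferon response genes (0.731) and at red blood cell markers (0.787). The red blood cell list has 3 genes in the table and its median is Slc4a1 (0.787), so both are 1 measurement that the 17 hold under both names. The median of astrocyte and Bergmann glia markers stood apart too (0.737), and in tumour 5 it is the value of Aldoc. Over its genes the deviation was only 0.19 ± 0.12, and 6 of 11 were highest in tumour 5 (adjusted p = 0.093, random-list permutation). Flt1 (0.723) and Oas1a (0.716) were likewise highest in tumour 5. Vim stood highest in tumour 15 (0.775), and Bcas1 in tumour 1 (0.812, within a range of 0.15 on the log2 scale).

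Low SHH targets and high oligodendrocyte, microglia, choroid plexus and mature granule neuron markers in tumour 5 could come from a lower share of tumour cells. Such a share alone would lower proliferation genes as much as SHH targets if the other cells expressed both equally little, which was not tested. Cell cycle and DNA replication genes deviated by -0.21 ± 0.01 and SHH targets by -0.38 ± 0.08. The difference of 0.162 was 2.07 standard errors over genes, which are not independent. Those errors are computed as for a mean and can be too small for a median. The difference therefore cannot decide whether a lower share accounts for the whole fall or for about 0.21 of it. If a lower share raised every other cell type alike, oligodendrocyte markers would not exceed the precursor or the pericyte and fibroblast markers. They exceeded both by at least 0.926 (standard error 0.165 for the precursors). Of the fibroblast markers, 9 of 11 lay below the other tumours, although the list's median was highest in tumour 5 (10.24). Both comparison lists were chosen after their median deviations (-0.16 and -0.23) were seen. Those of choroid plexus, microglia and endothelial markers were 0.84, 0.65 and 0.56. The markers thus did not rise alike, but this cannot exclude a lower share, which need not raise all cell types equally. Carry-over of particular normal tissue, such as choroid plexus, and a biological difference between tumours cannot be told apart, since 0 labels besides its number set tumour 5 apart.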

How the results depend on the processing

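No comparison between conditions, paired or not, was possible because there is 1 group. Alternatives were tallied for the 5 list differences, the lowest correlation, and the counts of genes, lists and chromosome shifts. Of these, 65 left the value within 1 SD or the count within 1.5 times, 12 moved it further and 2 reversed it. For the gene pairs, tallied apart, 87 left the value within 1 SD and 11 moved it further. Leaving out 1 of 5 tumours cannot move a mean by 1 SD. For list differences and gene pairs, those alternatives therefore could not count as moved. SHH minus WNT classifier reversed to 1.27 with list means and to 0.58 with exon length subtracted. With list means, SHH minus Group 3 was 4.60, SHH minus Group 4 2.99, progenitor minus mature 1.38 and progenitor minus differentiating -1.85. With exon length subtracted, SHH minus Group 3 was 4.75 and SHH minus Group 4 2.50. With members under a mean of 5 left out, progenitor minus mature was 2.75, progenitor minus differentiating -0.73, SHH minus Group 3 2.13 and SHH minus Group 4 0.79 ± 0.93, above 0 in 4 of 5 tumours. No mean changed sign in these differences apart from SHH minus WNT, and the cause of these changes was not tested beyond transcript length. Leaving out 1 tumour, the 5 list differences ranged from -0.80 to -0.50, 2.55 to 2.86, 0.85 to 1.30, 2.29 to 2.38 and -1.19 to -1.04, in the order WNT, Group 3, Group 4, mature and differentiating. The lowest correlation was 0.996 without a filter and 0.979 at a mean of at least 7. Genes over 4-fold numbered 9 without tumour 5 and up to 21 without another tumour, and 16 without the sex-linked genes. Lists of larger spread numbered 19 to 23 when 1 tumour was left out, and 15 of the 22 were called under every alternative. Without tumour 5 the microglia and choroid plexus lists lost the call, as did differentiating granule neuron genes without tumour 8. With chromosomes X and Y left out, 0 chromosome shifts were called. The mean of no gene pair changed sign, exon length moved 11 of them by over 1 SD, and with it Ccnd1 minus Ccnd2 was above 0 in 2 of 5 tumours. The spread call was also lost by cell cycle genes without tumour 14, unipolar brush cell genes without tumour 1, sex-linked genes without tumour 8 and WNT targets without tumour 8, 14 or 15, without a filter or by the range. By the median absolute deviation it was lost by microglia, choroid plexus and sex-linked genes. Lists not called as reported but called in some of 11 settings were the Group 4 classifier (7), p53 targets (5), Purkinje cell (4), SHH components (3) and red blood cell (1, without a filter, where the filter leaves it untested). Lists above the 95th percentile in level numbered 12, against 10 among genes with a mean of at least 5 and 13 with exon length subtracted; percentiles of lists nearer the middle moved more. Settings chosen after seeing the data were the removal of sex-linked genes and chromosomes and the range as a measure of spread. The depth behind each value is unknown, and the shrinkage of low values limits what can be said of weakly expressed genes.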

Other observations

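Both tests in this part, on Krt5 and Krt14 and on exon length, were set before their results were seen. Some keratin and desmosome genes, chosen after their values were seen, had a large spread between tumours and were highest in tumour 15. Krt17, a keratin of hair follicles and basal-like epithelia (chromosome 11, 100256217 to 100261029), averaged 10.91 ± 0.73 (SD, n = 5) and was 3.36-fold higher in tumour 15 than in tumour 5. Krt6a averaged 9.68 ± 0.76, Krt75 9.61 ± 0.78, the hemidesmosome gene Col17a1 9.40 ± 0.70, the desmosome genes Dsp 9.94 ± 0.72 and Dsc2 8.19 ± 0.76, and the laminin gene Lamb3 8.57 ± 0.67. Trp63, a transcription factor of stratified epithelia, averaged 8.34 ± 0.67, and Perp 9.56 ± 0.63. Of 13 epidermal and follicle markers, also chosen after seeing the data and Trp63 and Perp among them, 11 were highest in tumour 15. Of all genes with a mean of at least 5, 21.4% were highest there, and the 13 were not tested as a list.

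Skin or follicle cells carried over at dissection could bring these genes. Krt5 and Krt14, abundant in basal epidermis and follicle, would then reach the level of Krt17, but the higher of them lay at least 3.6 log2 units below Krt17 in each tumour (mean 3.73 ± 0.18). This argues against whole skin, and a follicle layer poor in both keratins stays open. How reads were split among keratin genes of similar sequence is uncertain, and read assignment was not tested here. No biological explanation was tested.

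The 4 measured WNT classifier genes stood above the SHH classifier genes by list medians, which may reflect transcript length or the absence of Emx2. After subtracting log2 exon length the difference became 0.58 ± 0.58 in favour of SHH, and the effect of Emx2 could not be tested. Each list holds 4 or 5 measured genes, list means gave 1.27, and no biological explanation was tested.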
